A study of Aliivibrio fischeri with 16 samples.

How the data were processed

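Total RNA of Vibrio fischeri ES114 strains at early stationary phase was made into 16 libraries, per the labels' protocols, with a stranded total RNA kit that includes microbiome rRNA depletion. The deposited files hold, per library, a locus tag and the raw HTSeq count of reads per gene, with no normalization: every value was checked to be whole and not negative. The submitters' processing notes name DRAGEN 4.2.7, fastp 0.23.4, BWA 0.7.18 and HTSeq 0.6.1 without their roles. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. Counts of overlapping and antisense genes, and of any near-identical copies, are therefore uncertain. The sequences of the 2 annotated dnaK loci were not compared. Each file ends in 5 HTSeq summary lines, which stayed out of totals and tests: as shares of all reads, 2.75 to 5.44% had no feature, 4.49 to 11.9% were ambiguous, 1.53 to 35.1% were of low alignment quality and 0.094 to 0.247% were not aligned.

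Groups were taken from the strain labels, 4 libraries each. The labels say that single colonies of each strain were grown but not that the 4 replicates of a strain were separate cultures, so p-values measure the spread between these libraries. No 2 replicates held identical values, and every replicate pair differed by more than counting noise (chi-square per degree of freedom 15.9 to 193). All files share 3988 features; VF_C0001 is listed only in the rscS* files and was not tested. The 155 rRNA and tRNA features were left out. Of the 3833 genes left, 3650 had at least 10 counts' worth of CPM (1.26) in at least 4 libraries and a total of at least 15 counts, and were tested. Symbols and neighbouring genes came from the RefSeq gene table of assembly ASM1180v1, which matched 3911 features and left 77 unmatched; 1269 tested genes have a symbol. That table holds no product names, so lists that depend on them are incomplete. No coordinates are given, since the build of the counts is not named.

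The comparisons, gene lists, named-gene rule, model terms and first set of alternatives were chosen before the data were examined. The plan named a quasi-likelihood count test as the main test and a second count model as an alternative; neither was run. The cause lies in the bookkeeping of this work and not in the data. The deposited files carry a comma-separated extension but are tab-separated, an automated unit check could not read their count column, and after it rejected the unit counts the column was recorded under the unit other, which bars those 2 tests. In their place limma-voom (R 4.3.3, limma 3.58.1, statmod 1.5.0) was fitted to the counts with trimmed-mean-of-M-values scaling (trims 0.3 and 0.05), an offset of 0.5, 1 term per group over all 16 libraries with 12 residual degrees of freedom, and robust moderated variances. Benjamini-Hochberg adjusted p under 0.05 counts as changed. Adjusted p-values for genes are from limma. CPM are taken over scaled library totals. The interaction is the rtmR deletion minus wild-type effect less the rscS* deletion minus complemented effect. Of 35 fixed gene lists, 30 had at least 4 measured genes and entered camera with a preset correlation of 0.01, adjusted over the lists of each comparison; an estimated correlation and fry were run beside it. The lists overlap: 10 synthetase genes are also in amino acid biosynthesis. The list of iron and heme uptake holds hutG, hutI and hutC, symbols used for histidine utilization; the fixed lists were kept as written. The lists without enough members were chemotaxis (1 measured), porins (2), and cyclic di-GMP turnover, mobile elements, and rRNA and tRNA (0 each). Strain genes were tested by exact two-sided permutation of log2 CPM plus 0.5.

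VF_2432 was taken as rtmR from its levels in the labelled strains, after these were seen, because neither the labels nor the gene table name its locus. Its levels therefore do not test the strain labels, as those of a locus known in advance would. The genes named per comparison are VF_2432, rscS and 2 neighbours on each side; among called genes with a mean of at least 50 counts and no overlap between groups, the 8 largest rises and 8 largest falls; up to 4 members with the smallest adjusted p of each list that passed camera and of the syp, cellulose, lux, flagellum, RNA turnover and envelope lists; and the 5 genes per direction with the smallest adjusted p for the interaction.

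Replicate numbers were tested as pairs by correlating the deviations of same-numbered libraries from their group means. Only the rscS* deletion and the complemented strain had every correlation above 0.1 (0.11 to 0.23), with 3 of 4 libraries best matched by their own number, so the blocked value stands beside that comparison where it moved the count by over 1.5 times or changed a call. The block was fitted over all 16 libraries, so its terms also draw on groups whose numbers do not pair. The labels do not say what a shared number means.

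The code was tested on simulated counts with the real means and library sizes. Of genes simulated at a log2 change of 0.5, 1 and 2, the recovered shares were 37.3, 82.1 and 100% for deletion against wild type, 38.8, 80.6 and 90.9% for rscS* deletion against complemented, 26.9, 59.7 and 92.4% for the interaction and 34.3, 79.1 and 95.5% for rscS* deletion against deletion. Of 3420 unchanged genes, 14, 6, 4 and 12 were called, respectively. A shifted list was called in all 4, and 0 of 19 unshifted lists. The simulated genes were drawn independently, so this does not test lists whose genes are correlated. Alternatives covered scaling, filters on low counts, the libraries in the fit, the block, stricter calls, rRNA and tRNA kept, and each library left out. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.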

Results

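RtmR is a membrane-embedded RNA-binding protein of the RRM family in Vibrio fischeri, the light-organ symbiont of the Hawaiian bobtail squid. RNA was sequenced from strain ES114 grown with shaking in LBS medium to early stationary phase. The 4 strains were profiled with 4 libraries each: wild type, an rtmR deletion, an rtmR deletion in the rscS* background, and that same rscS* deletion carrying a FLAG-tagged copy of rtmR at the attTn7 site (the complemented strain). RscS is a sensor kinase that controls the syp symbiosis polysaccharide genes, and rscS* is used here as the biofilm-induced background. The counts do not measure biofilm. The 16 libraries held 5.56 to 23.8 M (mega) counts assigned to genes, with means of 8.49 ± 4.45 M in wild type, 15.8 ± 7.55 M in the rtmR deletion, 7.36 ± 1.21 M in the rscS* deletion and 7.45 ± 0.837 M in the complemented strain (SD, n = 4 each). The tmRNA gene ssrA took 10.8 to 18.1% of the counts, and rRNA up to 1.36%. The first principal component held 46.8% of the variance and the second 16.1%. On the first, wild type scored −42.4 to −9.4 and the rtmR deletion 6.59 to 28.1. The complemented strain, at 1.36 to 11.1, did not lie with wild type, and the rscS* deletion spanned −29.2 to 10.3. On the second, the 2 strains with rtmR scored 0.856 to 13.1 and the 2 without it −27.2 to −2.81.

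The transcript taken as rtmR, VF_2432, stood at 317 ± 57.4 CPM (counts per M counts of the library) in wild type and 12.4 ± 4.02 CPM in the rtmR deletion (SD, n = 4). In the rscS* background it stood at 2.09 ± 1.42 CPM in the deletion and 306 ± 37.1 CPM in the complemented strain, so the tagged copy gave a level close to the wild-type mean. The 4 wild-type libraries spanned 238 to 374 CPM and the 4 complemented libraries 275 to 359 CPM, against 9.36 to 18.1 CPM in the rtmR deletion and 1.00 to 4.17 CPM in the rscS* deletion. The fitted log2 fold change was −4.62 (SE 0.203) for deletion against wild type and −7.28 (SE 0.394) for rscS* deletion against complemented. Each difference separated all libraries, with an exact two-sided permutation p = 0.0286, the smallest that 70 splits of 4 against 4 libraries allow. The labels and the gene table pair no locus with the name rtmR, and VF_2432 was chosen after its values were seen. Its separation and the p-value follow from that choice, so they test neither the locus nor the labels. The gene rscS (VF_A0237) was at 11.3 ± 2.46 CPM in wild type, 24.1 ± 2.83 CPM in the rtmR deletion, 2021 ± 518 CPM in the rscS* deletion and 1951 ± 208 CPM in the complemented strain.

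**Figure D1:**
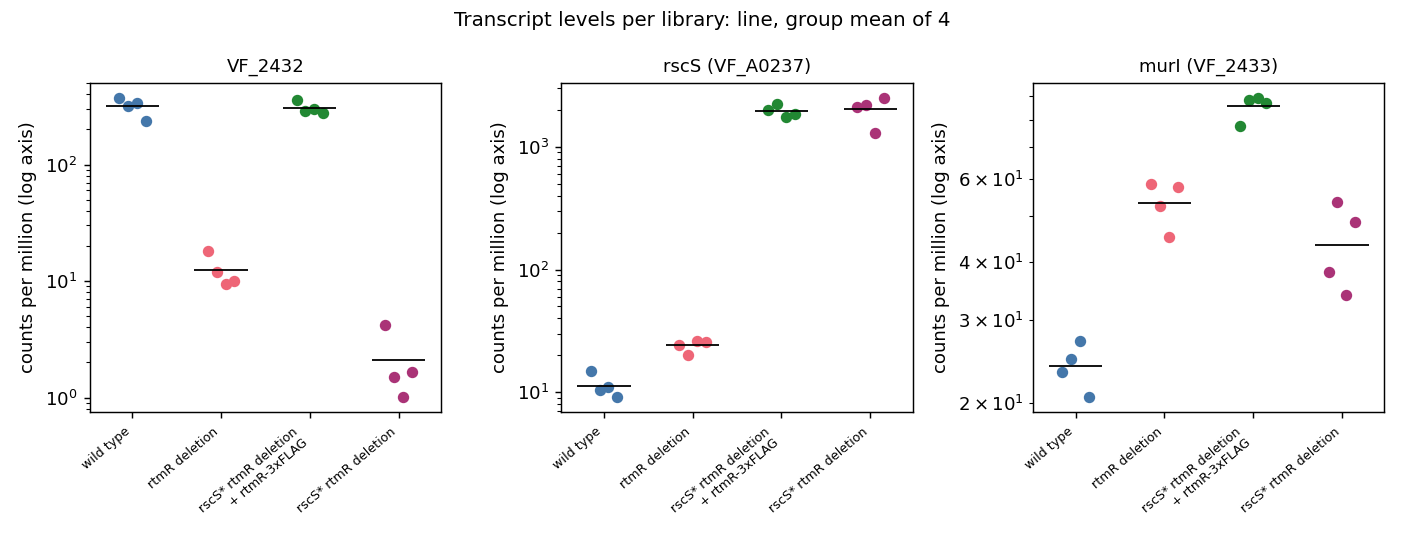
Transcript level of VF_2432, rscS and the neighbour gene murI in each of the 16 libraries (CPM, log axis); each point is 1 library and each line the mean of 4. VF_2432 lies between 238 and 374 CPM in wild type and between 1.00 and 4.17 CPM in the rscS* deletion.

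The neighbour of VF_2432 on one side, murI (VF_2433), encodes glutamate racemase, which supplies D-glutamate for peptidoglycan. It rose from 24.0 ± 2.76 to 53.4 ± 6.18 CPM in the rtmR deletion (log2 1.17, SE 0.147, adjusted p = 1.17e-05). In the rscS* background it was lower in the deletion than in the complemented strain, 43.5 ± 9.09 against 85.6 ± 5.29 CPM (log2 −1.01, SE 0.134, adjusted p = 9e-05). The next gene, VF_2434, was at log2 −0.52 in the first comparison, with a call at adjusted p = 0.0358 that was lost in 9 of 19 alternative fits, and at −0.44 in the second (adjusted p = 0.162). On the other side lie VF_R0024 and VF_T0095, an rRNA and a tRNA gene that were not tested.

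The comparison of the rtmR deletion with wild type asks which transcripts depend on rtmR in the native background, without rscS*. The stationary-phase sigma factor gene rpoS (VF_2067) fell from 824 ± 269 to 154 ± 25.2 CPM (log2 −2.39, SE 0.179, adjusted p = 7.64e-08). Of 54 ribosomal protein genes 29 fell and 1 rose, and of 20 aminoacyl-tRNA synthetase genes 16 fell and 2 rose (adjusted p = 0.65 with an estimated correlation for both lists). In the opposite direction, lptD (VF_0289), which encodes the outer membrane protein that inserts lipopolysaccharide, rose from 470.5 ± 24.9 to 811 ± 31.0 CPM (log2 0.79, SE 0.083). In all, 1786 of 3650 genes changed, 900 upward and 886 downward, of which 298 rose and 123 fell by at least 2-fold. The 4 deletion libraries did not overlap the 4 wild-type libraries in 1497 genes, 41% of those tested, where chance gives 2.86%.

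After VF_2432 the largest falls in the deletion were in VF_1480 (log2 −2.73), VF_0274 (−2.53), VF_2376 (−2.40), rpoS (−2.39), VF_0846 (−2.35), VF_2377 (−2.21) and VF_1112 (−2.11). VF_0274 went from 3039 ± 1010 to 514 ± 41.5 CPM and VF_1480 from 241 ± 52.6 to 35.8 ± 4.84 CPM. The largest rises were in genes with little transcript in wild type. They were VF_2655 (log2 4.73), VF_A0534 (4.48), VF_2631 (4.36), VF_B0036 (4.04), VF_A0634 (3.73), VF_A0877 (3.72), VF_A0670 (3.49) and VF_0607 (3.22). VF_2631 went from 1.18 ± 0.878 to 25.4 ± 18.4 CPM and VF_A0634 from 0.935 ± 0.621 to 13.5 ± 4.89 CPM. The call of VF_B0036 was lost without any one of wild-type libraries 2, 3 and 4 (adjusted p up to 0.0878 over its alternatives). The gene rscS itself rose by log2 1.00 (SE 0.220, adjusted p = 0.00138). The rscS* libraries of this series held 1290 to 2500 CPM of rscS, and carry-over of their reads into the rtmR deletion libraries was not tested.

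Among the ribosomal protein genes the count adjusted over the list alone was 32 lower and 1 higher, with a median log2 fold change of −0.45. Examples were rpsU (log2 −0.85), rpsQ (−0.67), rplA (−0.63) and rpsT (−0.57). The aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, had the same 16 falls and 2 rises adjusted over the list alone. Among them lysS fell by 1.11 on the log2 scale, leuS by 1.00, serS by 0.96 and trpS by 0.70. Both lists passed the camera test as lower (adjusted p = 0.00116 and 0.00115), but adjusted p = 0.65 with an estimated correlation for each. Both were lower again without rtmR deletion libraries 1 and 2 (adjusted p = 0.000843 for each).

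Of 10 glycolysis and gluconeogenesis genes 8 fell and 0 rose, with the same count adjusted over the list alone. They included enolase, eno (log2 −1.06), phosphoenolpyruvate carboxykinase, pckA (−0.84), pgi (−0.81) and pfkA (−0.80). Of 34 genes for sugar uptake 16 fell and 5 rose (16 and 6 adjusted over the list alone). Here the ribose-binding protein gene rbsB fell by 2.02 on the log2 scale, the glucose transporter gene ptsG by 1.53, glpT by 1.19 and glpK by 0.97. Of 23 purine and pyrimidine synthesis genes 13 fell and 0 rose (15 and 0 adjusted over the list alone), among them purB (log2 −1.46), pyrC (−1.19), pyrI (−0.93) and pyrE (−0.66). These 3 lists passed camera as lower (adjusted p = 0.00405, 0.0187 and 0.00214), each with adjusted p = 0.65 with an estimated correlation. Of 21 aerobic respiration and ATP synthase genes 8 fell and 1 rose (8 and 1 adjusted over the list alone), led by the cbb3-type oxidase genes ccoN (log2 −1.91), ccoO (−1.87) and ccoP (−1.38) and by petA (−1.40). Its call (adjusted p = 0.043; adjusted p = 0.65 with an estimated correlation) was lost without wild-type library 4 (0.121), without rtmR deletion library 1 (0.068) or 4 (0.0548), and without deletion libraries 1 and 2 together (0.0666).

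No other list passed camera in this comparison. The counts below stand beside 886 falls and 900 rises among all 3650 genes, and those of the flagellar and RNA turnover lists lie near these shares. In the envelope stress and outer membrane assembly list 7 of 20 genes rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.141). Beside lptD they included surA, a periplasmic chaperone gene (log2 0.41), and degS, which encodes the protease that senses misfolded outer membrane proteins (0.42), while bamC fell by 0.47. Of 32 flagellar genes 9 fell and 2 rose (8 and 2 adjusted over the list alone; adjusted p = 0.252), including fliO (log2 −1.65), flgA (−0.82), flgD (−0.56) and the anti-sigma factor gene flgM (−0.50). In the RNA turnover list 6 of 23 genes fell and 4 rose, with the same counts adjusted over the list alone (adjusted p = 0.252). The RNA pyrophosphohydrolase gene rppH was lower by log2 −0.80 and the RNase G gene rng by −0.60, whereas rnhB, for RNase HII, was higher by 0.65. Of the 14 measured syp genes 2 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.988). VF_A1025 was at log2 0.73, VF_A1022 at 0.46 and VF_A1030 at −0.98, and the last 2 calls were lost without wild-type library 1 and without either wild-type library 4 or rtmR deletion library 1, respectively. VF_A1031 was at log2 −0.40 (adjusted p = 0.112). Of 7 cellulose genes 2 rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.419), with bcsZ at log2 0.55, VF_A0881 at 0.34, bcsG at −0.78 and bcsE at 0.52 (adjusted p = 0.0513). Of 8 lux genes for light production 2 rose and 2 fell, with the same counts adjusted over the list alone (adjusted p = 0.587). VF_A0924 rose from 3.71 ± 0.979 to 13.1 ± 2.59 CPM (log2 1.73), VF_A0925 was at −0.82, VF_A0922 at −0.33, and VF_A0919 at 0.41 with a call lost in 8 of 19 alternative fits. Without rtmR deletion libraries 1 and 2 together, the calls of VF_A1022, VF_A1025, VF_A1030, VF_A0919, VF_A0922 and VF_A0925 were lost (adjusted p up to 0.0907, 0.0548, 0.29, 0.112, 0.0833 and 0.19 over their alternatives).

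The tests were limma-voom across all 16 libraries. Across genes, log2 fold changes in this comparison ran against mean expression (Spearman rho −0.31). That trend was not tested as a source of the list results. Reads of low alignment quality, which stayed out of the counts, made up 1.59 to 35.1% in the rtmR deletion libraries against 1.94 to 3.76% in wild type. Deletion libraries 1 and 2 held the highest shares (35.1 and 20.7%) and also the most rRNA (1.36 and 0.681% of counts). Without these 2 libraries 1098 genes changed. What the reads of low alignment quality are was not tested.

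**Figure D2:**
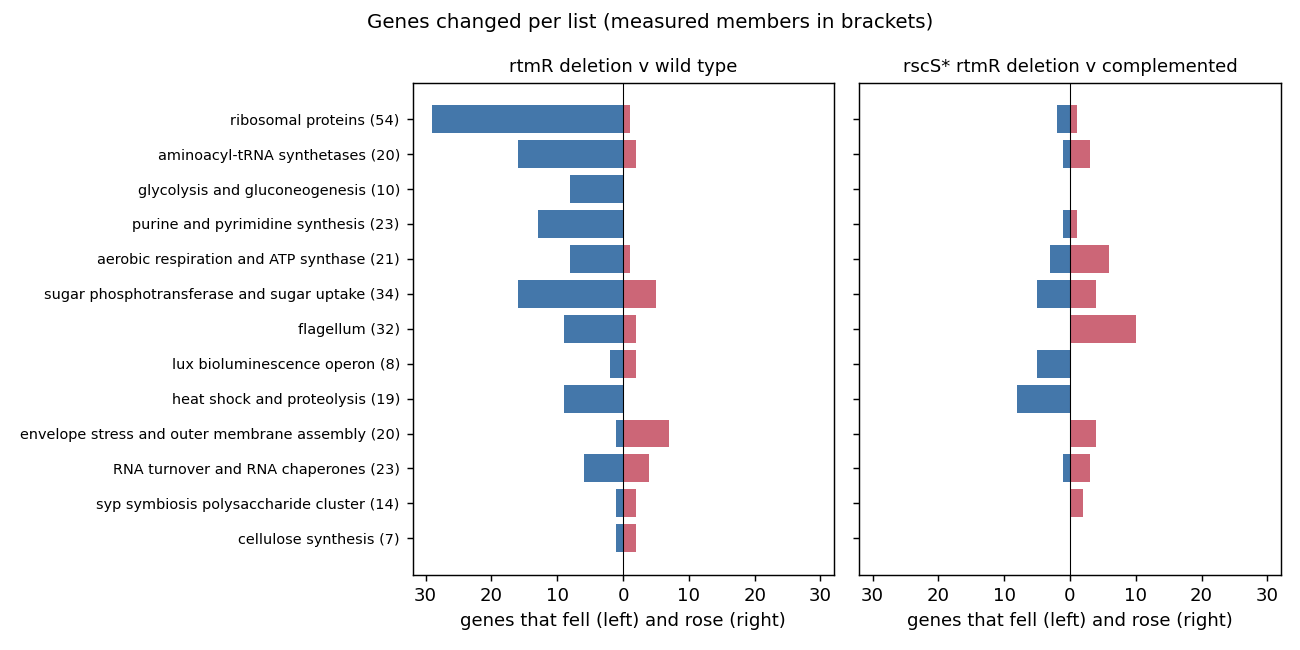
Number of genes per fixed list that fell (blue bars, left of 0) or rose (red bars, right of 0) in the rtmR deletion against wild type and in the rscS* deletion against the complemented strain; measured members are in brackets. Of 54 ribosomal protein genes 29 fell in the first comparison and 2 in the second.

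The comparison within the rscS* background asks which transcripts depend on rtmR there, with the complemented strain as the reference. Without rtmR, transcripts of the disulfide bond gene dsbB, the peptidase gene pepE and lptD were higher, 10 of 32 flagellar genes rose, and 5 of 8 lux genes and 8 of 19 heat shock genes fell. These 3 lists passed camera but had adjusted p = 0.23, 0.41 and 0.69 with an estimated correlation. The transcript of dsbB (VF_1635) rose from 24.8 ± 1.99 to 84.8 ± 9.95 CPM (log2 1.77, SE 0.132, adjusted p = 1.05e-07) and pepE (VF_A1068) from 63.1 ± 9.60 to 217 ± 26.3 CPM (log2 1.78, SE 0.130). As in the comparison with wild type, lptD was higher, at 812 ± 21.0 against 491 ± 6.72 CPM (log2 0.73, SE 0.0807, adjusted p = 1.42e-05). In all, 609 of 3650 genes changed, 358 upward and 251 downward, with 32 rising and 33 falling by at least 2-fold. With the replicate number as a block over all 16 libraries, 994 genes changed, 529 upward and 465 downward. That fit shares its block terms with wild type and the rtmR deletion, whose numbers do not pair, so it is not a paired test. With the block in these 8 libraries alone, 5 of the 46 named genes lost their call and 0 gained one. Libraries of the 2 groups did not overlap in 772 genes, 21.2% of those tested, where chance gives 2.86%. The groups also differed in reads of low alignment quality, 1.53 to 2.74% in the rscS* deletion against 3.19 to 8.91% in the complemented strain. Their tRNA shares were 0.0401 to 0.0531% against 0.0628 to 0.0815%. Whether these differences bear on the calls was not tested.

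The other large rises were in VF_A1190 (log2 2.06), VF_A0977 (1.71), VF_A0755 (1.70), VF_A0080 (1.55), VF_2099 (1.48) and VF_1288 (1.41). The largest falls after VF_2432 were in VF_1466 (−2.79), VF_A1074 (−2.17), VF_0172 (−2.13), VF_0171 (−2.07), VF_1467, an annotated dnaK copy (−1.92), the small heat shock protein gene ibpA (−1.76) and the biotin synthase gene bioB (−1.57). VF_1466 was at 33.0 ± 15.5 CPM against 259 ± 196 CPM and ibpA at 322 ± 53.7 against 1219 ± 714 CPM. Leaving out single libraries ended the call of VF_0172 (any 1 complemented library), of VF_1467 (any 1 rscS* deletion library or complemented library 2 or 3) and of VF_2099 (any 1 library except rscS* deletion library 3), with adjusted p up to 0.119, 0.115 and 0.116 over their alternatives. The block ended the call of VF_1467, and with the block in a fit of these 8 libraries alone, chosen after the data were seen, those of VF_0171, VF_0172, VF_1466 and ibpA were lost too (adjusted p up to 0.0977, 0.119, 0.0797 and 0.062).

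Of 8 lux genes 5 fell and 0 rose, with the same count adjusted over the list alone. They included VF_A0925 (log2 −0.96), VF_A0921 (−0.94), VF_A0922 (−0.71) and VF_A0919 (−0.70). The list passed camera as lower at adjusted p = 0.000224, with adjusted p = 0.41 with an estimated correlation. Of 32 flagellar genes 10 rose and 0 fell (11 and 0 adjusted over the list alone), with camera adjusted p = 0.000628 but adjusted p = 0.23 with an estimated correlation. The basal body gene fliE rose by log2 1.11, the motor switch gene fliG by 0.87, the export gate gene flhA by 0.66 and fliH by 0.63. Of 19 heat shock and proteolysis genes 8 fell and 0 rose (9 and 0 adjusted over the list alone), with camera adjusted p = 0.00933 but adjusted p = 0.69 with an estimated correlation. Beside ibpA these were led by dnaK (VF_1994, log2 −0.86), hslR (−0.81) and hslO (−0.61); the call of hslR was lost without rscS* deletion library 1 (adjusted p = 0.0516, the highest over its alternatives). With the block all 3 lists passed again, among 5 in all.

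In the envelope list 4 of 20 genes rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.28). Next to lptD stood rseP, for the intramembrane protease that releases sigma E (log2 0.54), bamA, the outer membrane protein insertase gene (0.38), and bamD (0.35). The call of bamA was lost without rscS* deletion library 3 or 4 or complemented library 1 or 2, and that of bamD without rscS* deletion library 1 or 2 or complemented library 2, 3 or 4 (adjusted p up to 0.0888 and 0.103 over their alternatives). In the RNA turnover list 3 of 23 genes rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.925). The transcript of rnhB was higher by log2 0.86, of rne, for RNase E, by 0.39 and of rnc, for RNase III, by 0.39, while hfq, for the RNA chaperone, fell by 0.50. The call of rne was lost without any 1 of rscS* deletion libraries 2, 3 and 4 or complemented libraries 1, 2 and 3, and that of rnc without rscS* deletion library 3 or complemented library 3 (adjusted p up to 0.0962 and 0.0676 over their alternatives). Of 14 syp genes 2 rose and 0 fell, with the same count adjusted over the list alone (adjusted p = 0.59). VF_A1020 rose from 1.24 ± 0.629 to 3.17 ± 0.559 CPM (log2 1.45) and VF_A1023 from 3.41 ± 0.976 to 6.10 ± 0.437 CPM (0.88), the second call being lost without complemented library 4 (adjusted p = 0.0552, the highest over its alternatives). VF_A1021 was at log2 0.71 (adjusted p = 0.0881) and VF_A1034 at 0.78 (adjusted p = 0.203). None of the 7 cellulose genes was called by limma over all genes or over the list alone, with bcsQ at log2 0.49 (unadjusted p = 0.0274 from limma), bcsA at 0.33 (0.0918), bcsG at 0.32 (0.0535) and bcsZ at 0.12 (0.307). The transcript of rscS was at log2 0.02 (SE 0.174, adjusted p = 0.968).

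**Figure D3:**
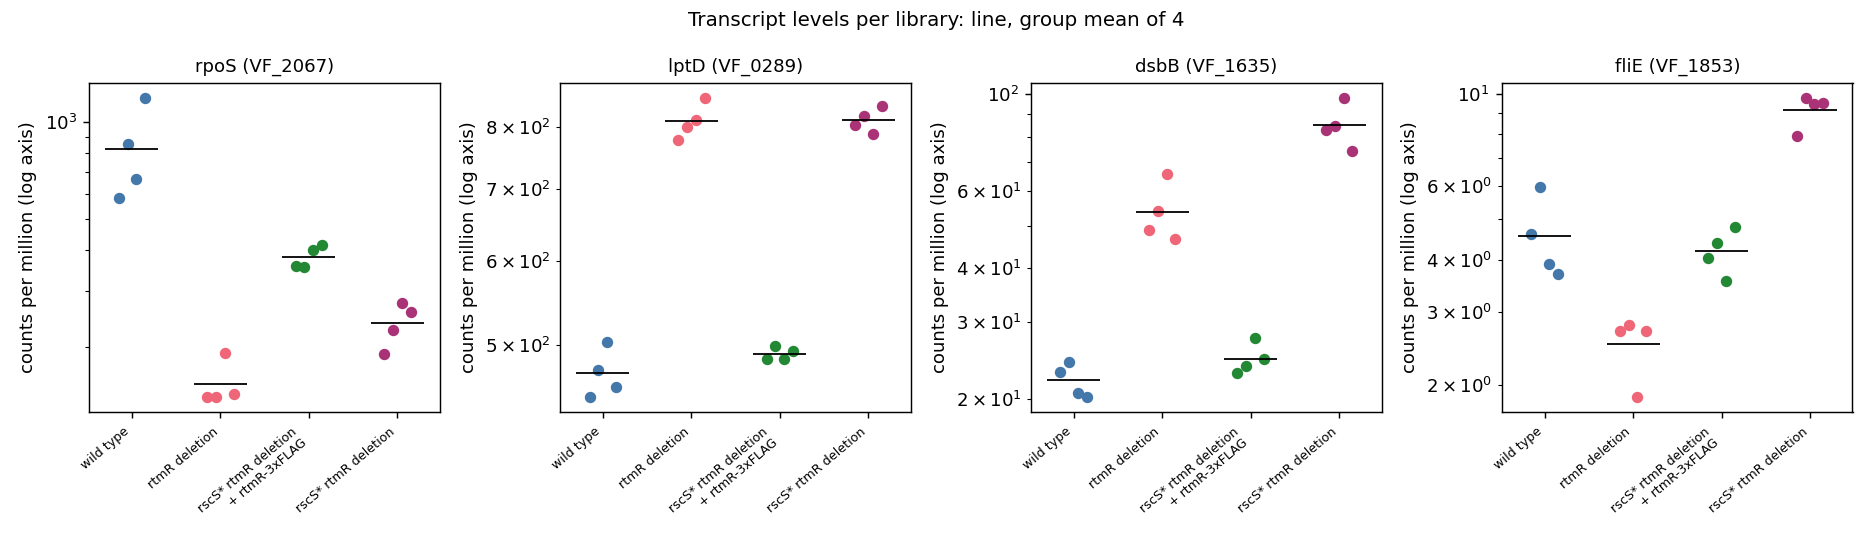
Transcript level of rpoS, lptD, dsbB and fliE in each of the 16 libraries (CPM, log axis); each point is 1 library and each line the mean of 4. The lptD means are 470.5 and 491 CPM in the strains with rtmR and 811 and 812 CPM in those without it.

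The response to rtmR loss was then compared between the native and rscS* backgrounds, as the deletion minus wild-type effect less the rscS* deletion minus complemented effect. The 2 responses shared more genes in the same direction than in opposite ones. Among genes called in both, 164 rose in both (88.3 by chance for independent lists), 137 fell in both (60.9 by chance), 20 rose and then fell (61.9) and 16 fell and then rose (86.9). That made 301 genes with the same sign and 36 with opposite signs, or 89.3% of the shared calls. With the replicate number as a block over all 16 libraries, 416 had the same sign and 181 opposite signs. The numbers pair only the libraries of the rscS* comparison. The 2 comparisons have no library in common. Of the shared genes, dsbB rose by log2 1.25 and 1.77, the spermidine acetyltransferase gene speG by 1.73 and 1.25, tilS, for a tRNA-modifying enzyme, by 1.07 and 1.05, and ribD, of riboflavin synthesis, by 1.06 and 1.06. VF_1480 was at −2.73 and −1.52, dnaK (VF_1994) at −1.17 and −0.86, and groL, for the GroEL chaperonin, at −0.91 and −0.87. Other than dsbB, VF_1480 and dnaK, these shared genes were singled out after their values were seen. By list, 5 of 19 heat shock genes and 5 of 34 sugar uptake genes fell in both, against 137 of all 3650 genes. Of 79 amino acid biosynthesis genes 7 rose in both, the synthetase gene thrS among them, and the synthetase gene trpS fell in both, against 164 of 3650 that rose.

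Across all 3647 genes other than VF_2432 and its 2 measured neighbours, the fold changes of the 2 comparisons were nearly unrelated (Pearson r = −0.06, Spearman rho = 0.069, across genes, which are not independent replicates). Without rscS* deletion library 3 the r was 0.19.

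By the interaction test the response differed between backgrounds for 1092 genes, 521 with a higher and 571 with a lower log2 fold change in the native background. Other splits of the libraries did not exclude chance for such a difference, since 1 of them gave 1344 genes. With upper-quartile scaling that split was 639 and 398. The gene murI had the smallest p (log2 difference 2.17, SE 0.198, adjusted p = 8.03e-06), rising in the native background and falling in rscS*. It lies next to VF_2432, taken as rtmR. The native pair differs in the deletion itself, whereas both rscS* strains carry it and differ in a copy at attTn7. For murI a local effect of the deletion cannot be told apart from a response to rtmR loss. Higher in the native background were also VF_0303 (1.54), VF_A0485 (1.24), VF_1426 (1.21) and VF_1511 (1.19). Lower there were fliE (−1.92), rpoS (−1.70), VF_2218 (−1.39), VF_1177 (−1.29) and VF_1665 (−1.08). The rpoS transcript fell in both backgrounds (log2 −2.39 and −0.70), from 824 ± 269 CPM in wild type and from 383 ± 30.3 CPM in the complemented strain. The transcript of fliE fell in the native background (log2 −0.81, adjusted p = 0.00326) and rose by 1.11 in rscS*. The gene VF_2432 itself differed by 2.66, and rscS by 0.99 (adjusted p = 0.0177), a call lost without wild-type library 4 (0.0507). Carry-over of rscS reads from rscS* libraries was not tested here either.

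Lists with a lower response in the native than in the rscS* background by camera were the aminoacyl-tRNA synthetases (13 of 20 genes lower, 0 higher; 14 and 0 adjusted over the list alone), the flagellum (11 of 32 lower, 0 higher; 13 and 0), aerobic respiration (9 of 21 lower, 0 higher; 13 and 0), purine and pyrimidine synthesis (10 of 23 lower, 0 higher; 10 and 0) and fatty acid and phospholipid synthesis (7 of 18 lower, 1 higher; 9 and 2). For these 5 lists adjusted p = 0.25 (flagellum) and 0.56 (the other 4) with an estimated correlation. The same direction held for glycolysis (4 of 10 lower, 0 higher; 6 and 0), sugar uptake (13 of 34 lower, 3 higher; 13 and 3), the TCA cycle (4 of 11 lower, 0 higher; 4 and 0), amino acid biosynthesis (14 of 79 lower, 3 higher; 10 and 3) and ribosomal proteins (6 of 54 lower, 3 higher; 1 and 0), the last pair in each bracket being adjusted over the list alone. Here adjusted p = 0.56 for glycolysis and sugar uptake, 0.57 for the TCA cycle, 0.66 for amino acid biosynthesis and 0.73 for ribosomal proteins with an estimated correlation. Among all 3650 genes 571 were lower and 521 higher. The ribosomal protein genes held a smaller share of lower calls than that, and their list passed by its shift (median log2 difference −0.28). The lux list was higher in the native background (6 of 8 higher, 0 lower; 6 and 0 adjusted over the list alone), as was plasmid pES100 (13 of 54 higher, 2 lower; 13 and 2), both with adjusted p = 0.56 with an estimated correlation. Examples were serS (log2 difference −1.03), asnS (−1.05), fliO (−2.05), ccoO (−1.52), purB (−1.38), fabF of fatty acid elongation (−1.07), ptsG (−1.31), sdhC of succinate dehydrogenase (−1.21), VF_A0924 (2.33) and VF_B0006 (1.29). Camera adjusted p was 6.4e-05 for the synthetases, 0.000326 for the flagellum and for aerobic respiration, 0.00161 for lux, 0.00303 for purines and pyrimidines, 0.0131 for fatty acids and for glycolysis, 0.0167 for sugar uptake, the TCA cycle and pES100, and 0.0216 for amino acid biosynthesis and ribosomal proteins. The call of ribosomal proteins was lost without wild-type library 4 (0.148), rscS* deletion library 3 (0.161) or rtmR deletion library 1 (0.0545), that of amino acid biosynthesis without the first 2 of these (0.115 and 0.0769), and that of pES100 without wild-type library 1 (0.0595). Without rscS* deletion library 3 and wild-type library 4 together, the TCA cycle (0.0566) and sugar uptake (0.0654) were lost. With all 16 libraries fry gave 0.249 for ribosomal proteins and 0.11 for amino acid biosynthesis, a list that holds 10 of the synthetases. With the gene length trend removed, sugar uptake (0.0659) and amino acid biosynthesis (0.0881) were lost.

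Some lists that did not pass camera held called genes too. Of 27 anaerobic respiration and fermentation genes 9 were lower and 1 higher (camera adjusted p = 0.218). Of 5 biofilm regulators outside syp, a list that holds rscS, 4 were higher and 1 lower (camera adjusted p = 0.0697). Among the syp genes VF_A1020 (log2 difference −1.84), VF_A1023 (−1.28) and VF_A1030 (−1.46) were lower and 0 of 14 higher. Among envelope genes 3 of 20 were higher and 3 lower (3 and 4 adjusted over the list alone), with the sigma E gene rpoE at 1.11, lptA at 0.57, bamC at −0.57 and bamD at −0.51, and lptD at 0.06 (adjusted p = 0.714). In the RNA turnover list 5 of 23 were lower and 0 higher, including rppH (−0.97), polynucleotide phosphorylase, pnp (−0.93), eno (−0.86) and rng (−0.51). For cellulose genes the difference was −1.10 for bcsG, 0.43 for bcsZ (adjusted p = 0.045), 0.56 for bcsE (0.157) and 0.30 for VF_A0881 (0.119). The call of bcsZ was lost in 14 of 26 alternative fits and that of VF_A1030 in 10 of 25 (adjusted p up to 0.17 and 0.141), most of them without a single library. The call of bamD was lost without wild-type library 3 or complemented library 4 (up to 0.126). Without rtmR deletion libraries 1 and 2 the calls of VF_A1020, VF_A1023, rpoE, lptA, rng, pnp, eno and asnS were lost as well, among 30 of the 73 genes named by rule for the interaction. The reference strain of the rscS* pair carries a tagged copy at another site, so the contrast holds that change too. The count was 659 without rscS* deletion library 3 and wild-type library 4, and 332 without rtmR deletion libraries 1 and 2.

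**Figure D4:**
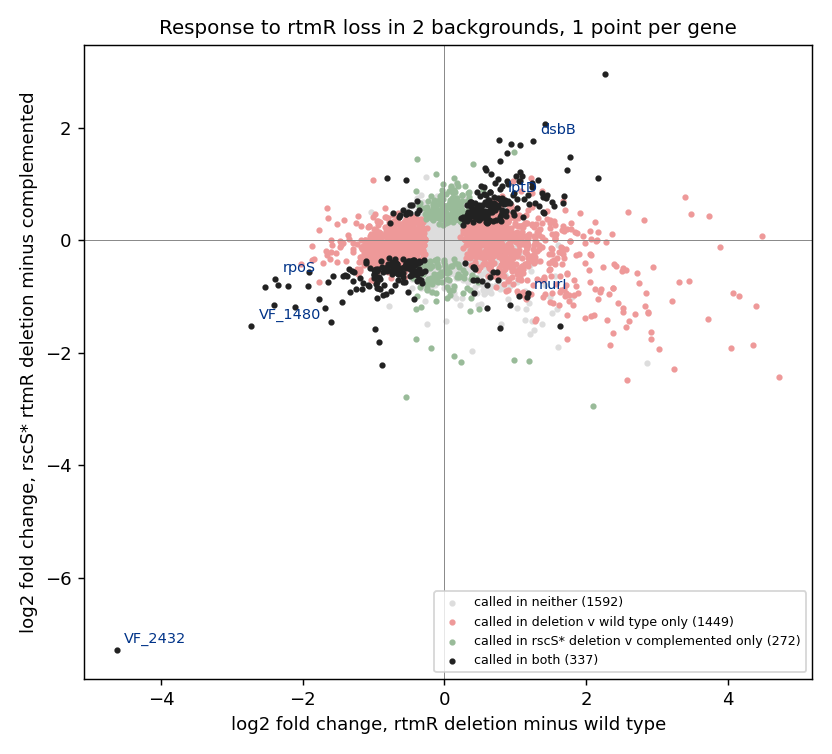
Log2 fold change of each of 3650 genes in the rtmR deletion against wild type (horizontal axis) and in the rscS* deletion against the complemented strain (vertical axis). Black points are the 337 genes called in both, of which 301 have the same sign.

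The last comparison, which the design text does not name, sets the rscS* deletion against the rtmR deletion, strains that by their labels both lack rtmR and differ in rscS*. The rscS transcript rose by log2 6.38 (SE 0.173, adjusted p = 7.23e-15) and 10 of 32 flagellar genes rose. The basal body gene fliE went from 2.52 ± 0.433 to 9.16 ± 0.849 CPM (log2 1.81, SE 0.180, adjusted p = 1.01e-05) and the chaperone gene fliS from 5.49 ± 1.47 to 11.9 ± 1.08 CPM (1.22; a call lost without rtmR deletion libraries 1 and 2, adjusted p = 0.055). In all, 421 genes changed, 207 upward and 214 downward, of which 12 rose and 50 fell by at least 2-fold. That count was 42 in a fit of these 8 libraries alone, 9 without rtmR deletion libraries 1 and 2, and 148, 190, 934 and 177 without rtmR deletion library 1, 2, 3 and 4 in turn; it was 175 and 246 without rscS* deletion library 2 and 3. Of the 59 genes named by rule in this comparison, 33 lost their call in the fit of 8 libraries and 40 without rtmR deletion libraries 1 and 2. Libraries of the 2 groups did not overlap in 442 genes, 12.1% of those tested, where chance gives 2.86%.

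Other rises were in VF_1863 (log2 1.59), VF_1855 (1.26), VF_A0080 (1.18), VF_1866 (1.12) and VF_A0081 (1.11). Falls were largest in VF_2432 (−2.69), VF_1440 (−2.62), VF_0607 (−2.35), mutT (−2.10), VF_1542 (−1.62), mltC (−1.53), VF_2007 (−1.35) and VF_A0757 (−1.35). The rises in VF_A0080, VF_A0081 and VF_1866 and every fall here but that of VF_2432 lost their call without rtmR deletion libraries 1 and 2 together, and VF_1440, VF_0607, mutT, VF_1542, VF_2007 and VF_A0757 also in the fit of 8 libraries. Single libraries ended the calls of VF_1440 (any but rscS* deletion 4 and rtmR deletion 3), VF_1542 (rscS* deletion 3, rtmR deletion 1, 2 or 4) and VF_2007 (rscS* deletion 2 or 3, rtmR deletion 1 or 2), with adjusted p up to 0.304, 0.33 and 0.359 over their alternatives. Of 32 flagellar genes 10 rose and 0 fell (17 and 0 adjusted over the list alone), among them fliG (log2 0.80) and fliF (0.61), whose calls were lost without rtmR deletion libraries 1 and 2. This list passed camera (adjusted p = 5.16e-08) and held at adjusted p = 0.019 with an estimated correlation. Of 8 lux genes 4 fell and 0 rose (5 and 0 adjusted over the list alone; camera adjusted p = 0.0025, and adjusted p = 0.47 with an estimated correlation), with VF_A0924 at log2 −1.14, VF_A0921 at −0.86, VF_A0919 at −0.60 and VF_A0923 at −0.32. Of 54 pES100 genes 7 fell and 1 rose (10 and 1 adjusted over the list alone; adjusted p = 0.00042, and adjusted p = 0.47 with an estimated correlation), including VF_B0020 (−1.99), VF_B0050 (−0.80), VF_B0040 (−0.73) and radC (0.63). Each lux and pES100 gene named here lost its call in the fit of 8 libraries and without rtmR deletion libraries 1 and 2 together. Leaving out 1 library ended the call of VF_A0919 (rscS* deletion 1 or 3, rtmR deletion 1 or 4), VF_A0923 (any of the 8), VF_B0020 (rscS* deletion 2, 3 or 4, rtmR deletion 1, 2 or 4), VF_B0040 (rscS* deletion 1, rtmR deletion 1) and VF_B0050 (rtmR deletion 1), with adjusted p up to 0.172, 0.271, 0.29, 0.255 and 0.166 over their alternatives.

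A further 4 lists passed camera as higher in the rscS* deletion. Of 21 aerobic respiration genes 3 rose and 0 fell (5 and 0 adjusted over the list alone; adjusted p = 0.00108, and adjusted p = 0.62 with an estimated correlation), namely ccoO (log2 0.83), cydA (0.65) and ccoN (0.62). Of 27 anaerobic respiration and fermentation genes 5 rose and 0 fell (6 and 0 adjusted over the list alone; adjusted p = 0.0237, and adjusted p = 0.12 with an estimated correlation), among them the fumarate reductase gene frdC (0.76) and nrfF (0.75), nrfB (0.46) and nrfD (0.42) of nitrite reduction. Of 20 aminoacyl-tRNA synthetase genes 2 rose and 0 fell (0 and 0 adjusted over the list alone; adjusted p = 0.00108, and adjusted p = 0.69 with an estimated correlation), serS (0.51) and lysS (0.50). Of 79 amino acid biosynthesis genes 4 rose and 1 fell (1 and 1 adjusted over the list alone; adjusted p = 0.0351, and adjusted p = 0.69 with an estimated correlation), with glnA at 0.54, leuO at 0.47 and argC at −0.74; this call was lost without rscS* deletion library 3 (0.34) or rtmR deletion library 1 (0.0998). With fry the synthetases were at adjusted p = 0.127 and amino acid biosynthesis at 0.159. Each gene named from these 4 lists lost its call in the fit of 8 libraries and without rtmR deletion libraries 1 and 2 together. Leaving out any 1 of rscS* deletion libraries 2 and 3 and rtmR deletion libraries 1, 2 and 4 ended the calls of cydA, lysS, serS, ccoO, ccoN and glnA, the last 3 also without rscS* deletion library 4. The call of nrfB was lost without rscS* deletion library 2 or 3 or rtmR deletion library 2, and that of frdC without rscS* deletion library 2 or rtmR deletion library 1. Of the syp genes, which RscS controls, VF_A1020 (log2 1.68) and VF_A1023 (0.87) rose and 0 of 14 fell (3 and 0 adjusted over the list alone; adjusted p = 0.108), with VF_A1030 at 0.76 (adjusted p = 0.123) and VF_A1021 at 0.69 (0.0642). The call of VF_A1023 was lost without rtmR deletion library 1 and in the fit of 8 libraries, and both calls without rtmR deletion libraries 1 and 2 (adjusted p up to 0.284 for VF_A1023 and 0.238 for VF_A1020). Of 7 cellulose genes bcsG rose (log2 0.76; 3 rose adjusted over the list alone; list adjusted p = 0.0733), a call lost in the fit of 8 libraries (up to 0.0996), with bcsQ at 0.49 (adjusted p = 0.0804), bcsA at 0.45 (0.0872) and bcsB at 0.19 (0.272).

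In the envelope list bamE rose by log2 0.57, rpoE was lower by −0.79 and the phage shock gene pspB by −0.97 (2 higher and 5 lower adjusted over the list alone), with lptA at −0.35 (adjusted p = 0.0611). The call of pspB was lost without any 1 of rscS* deletion libraries 2 and 4 and rtmR deletion libraries 1, 2 and 4, and that of bamE in the fit of 8 libraries (adjusted p up to 0.445 and 0.242). In the RNA turnover list rppH rose by 0.48, a call lost, like that of rpoE, without any 1 of rscS* deletion libraries 2 and 3 and rtmR deletion libraries 1, 2 and 4, and 0 of 23 genes were called adjusted over the list alone. The gene murI was at −0.33 (adjusted p = 0.106) and VF_2434 at 0.22 (0.461).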

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

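The thinning, the removal of the length trend, the tests of the short genes in the rscS* background, of the label and purity of rscS* deletion library 3 and of the VF_2432 reads were chosen only after the data were seen; the splits were planned.

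Within groups of 4 libraries, 14 of 174 tested sets held a library far from the other 3 relative to their range, where about 1 in 20 (8.7) is expected by chance. Wild-type library 1 had 15.1 M counts (others 5.56 to 6.98), 1.58 CPM of VF_B0036 (0.362 to 0.391) and 1140 CPM of VF_2218 (1510 to 1580). In rscS* deletion library 1, fliE was at 7.90 CPM (9.46 to 9.78). In rscS* deletion library 3, principal component 1 was −29.2 (5.55 to 10.3) and component 2 −27.2 (−10.9 to −9.11), with VF_0172 at 3.15 CPM (32.9 to 40.6) and VF_1542 at 0.86 CPM (5.93 to 7.02). In rtmR deletion library 3 the scaling factor was 1.06 (1.12 to 1.13), rpoS was at 192 CPM (140 to 143), fliE at 1.87 (2.70 to 2.79), mutT at 2.75 (5.54 to 6.28) and VF_1866 at 12.9 (8.37 to 9.02). In rtmR deletion library 1, fliS was at 3.32 CPM (5.93 to 6.45).

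The response to rtmR loss differed between backgrounds for 1092 genes by the interaction test, among them murI (log2 difference 2.17), VF_0303 (1.54), VF_A0485 (1.24), VF_1426 (1.21), VF_1511 (1.19), fliE (−1.92), rpoS (−1.70), VF_2218 (−1.39), VF_1177 (−1.29) and VF_1665 (−1.08). For murI, the neighbour of VF_2432, a local effect of the deletion cannot be told apart from such a response. The feature VF_C0001, listed for the rscS* libraries alone and not tested, averaged 2271 CPM over those 8 libraries (1868 to 2892).

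Other splits of the same libraries were fitted in the same way. For deletion against wild type, 1 of 35 splits, the real one, gave as many as 1786 genes (highest other 336). Chance can be excluded there at a share under 0.05, with 1 of 35 the smallest share possible. For rscS* deletion against complemented, 1 of 35 gave as many as 609 (highest other 0). These libraries pair by number, and of the 8 splits that part all 4 pairs the real one alone gave as many (highest other 0). As 8 splits are too few for a share under 0.05, they cannot exclude chance for this comparison. For rscS* deletion against rtmR deletion, 3 of 35 splits gave as many as 421, the highest other being 586, so chance cannot be excluded; both larger splits, 586 and 455, put rtmR deletion library 3 with rscS* deletion libraries. For the interaction, 2 of 100 splits gave as many as 1092, the highest other being 1344. That split kept deletion and wild type as labelled and put rscS* deletion library 3 with complemented libraries 1, 3 and 4. The splits drew labels anew in both backgrounds at once and did not keep the numbered pairs. A low share therefore speaks to any effect of rtmR, and chance cannot be excluded by it for a difference between backgrounds. The larger split shows a structure that follows rscS* deletion library 3.

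Genes of at most 300 bp lay above the rest in the rtmR deletion against wild type, by a median log2 difference of 0.32 (0.21 to 0.48 without single libraries; 244 genes, of which 75 rose and 41 fell). The rtmR deletion libraries were deeper, but after thinning every library to the smallest total the difference was 0.31 (at least 0.17 without single libraries), which argues against depth. In the rscS* background the difference was −0.2 (at most −0.077), which argues against a rise of short genes with rtmR loss in both backgrounds. With the length trend removed per library 1829 genes were called against 1786, which argues against the trend as the source of the calls. Log2 fold changes also ran against mean expression across genes (Spearman rho −0.31, and −0.15 with length), and removal of that trend was not tried. In the rscS* background the values were 0.15 with expression and 0.18 with length. A difference in RNA quality between the rtmR deletion and wild-type libraries was not tested and stays open, as does an effect of rtmR in the native background.

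Library 3 of the rscS* deletion lay 1.67 times as far from the mean of its group as the next farthest (distance 0.769 against 0.399 to 0.461). Its rscS level of 1290 CPM, against at most 26.3 CPM in the libraries without rscS*, argues against a wrongly labelled library of such a strain. Its VF_2432 level of 0.317% of the wild-type mean argues against wild-type or complemented cells mixed in. With the length trend removed the ratio was 1.62, which argues against that trend. No biological explanation was tested.

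The rtmR deletion libraries held 12.4 CPM of VF_2432 against 2.09 CPM in the rscS* deletion. The difference of 6.6 standard errors argues against a remnant of the gene transcribed to the same level in both strains as the only source. It cannot speak to a shared remnant with different transcript levels, which was not tested. The ratio of excess VF_2432 to excess rscS was 3.1 to 7.81 times that of the complemented libraries, which argues against reads from those. Reads from wild-type cells or libraries cannot be told apart from other sources. VF_2432 stood at 3.9% of the wild-type mean, and 0 genes with a wild-type mean of at least 50 counts had a smaller share left.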

How the results depend on the processing

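Leaving out 2 libraries together, thinning, removing the length trend and the block in a restricted fit were chosen after the data were seen. Over 5127 values of named genes under the alternatives, 4730 stayed on their side of the threshold, 355 lost a call and 42 gained one, and in 0 did a called gene change direction. The 2 planned count tests were not run, because the count column was recorded under another unit after an automated check could not read it. How far their calls differ from those of limma-voom is therefore not known. The restricted fit has no separate value for the interaction, which uses all 4 groups. In simulated data, where 3420 of 3650 genes were unchanged, 26.9 to 38.8% of genes changed by log2 0.5 were recovered. The real comparisons called 421 to 1786 genes, which loosens the Benjamini-Hochberg cutoff. The simulated shares therefore do not carry over to them, and the share of small changes missed is not known.

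In a fit of the 8 libraries compared, 42 genes changed between the deletion strains (421 with all 16 libraries). With a replicate block over all 16 libraries 994 genes changed for rscS* deletion against complemented. The count was 1004 for rscS* deletion against deletion, whose numbers do not pair. With that block 10 lists passed for deletion against wild type and 5 for rscS* deletion against complemented. Among the 46 named genes of the paired comparison the block ended 1 call, VF_1467, and added 1. With the block 416 shared calls had the same sign and 181 opposite signs. Without rscS* deletion library 3 and wild-type library 4 the interaction count was 659 and the correlation 0.22. Without rtmR deletion libraries 1 and 2 the counts were 1098 for deletion against wild type, 332 for the interaction and 9 for the deletion strains. The cause was not tested for these changes.

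Stricter calls leave fewer genes by construction: at least 2-fold, 421 for deletion against wild type, 65 for rscS* deletion against complemented, 441 for the interaction and 62 for the deletion strains; at adjusted p under 0.01, 267, 258 and 58 for the last 3, and 130 shared calls with the same sign. At 50 counts or more the correlation was 0.029. Camera with an estimated correlation passed 0 lists for deletion against wild type, 0 for rscS* deletion against complemented, 0 for the interaction and 1 for the deletion strains, against 6, 3, 12 and 7 with the preset one; fry passed 18 and 7 for the first 2. The cause was not tested.

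Without single libraries the counts were 1483 to 1902 for deletion against wild type, 414 to 561 for rscS* deletion against complemented, 759 to 1398 for the interaction and 148 to 934 for the deletion strains. The correlation was −0.15 (without rscS* deletion library 4) to 0.19 (without rscS* deletion library 3), and shared calls with the same sign 227 to 325. Lists passing were 5 to 9, 3 to 5, 10 to 12 and 7 to 11.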

Other observations

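The genes in the first 3 paragraphs were chosen after their values were seen. Several chaperone genes fell without rtmR in both backgrounds. Of the 19 heat shock and proteolysis genes, 5 fell in both: groL (log2 −0.91 and −0.87, native and rscS* background), dnaK (VF_1994, −1.17 and −0.86), htpG (−0.66 and −0.71), hslR (−0.86 and −0.81) and hslO (−0.74 and −0.61). The heat shock sigma factor gene rpoH fell in the native background (log2 −0.61, SE 0.117) and was at −0.21 in rscS* (adjusted p = 0.222). The disaggregase gene clpB was at 0.13 (adjusted p = 0.627) and fell in rscS* (−0.82, SE 0.213).

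In the list of iron and heme uptake, the ferrous iron transporter gene feoB fell from 446 to 146 CPM in the rtmR deletion (log2 −1.66, SE 0.269, adjusted p = 0.00018) and was at 0.58 in rscS* (adjusted p = 0.147). The repressor gene fur fell by 0.59 and was at −0.10 in rscS* (adjusted p = 0.646). The members hutG (log2 1.44 and 0.75) and hutI (1.03 and 0.57) rose in both backgrounds and hutC (−0.32 and −0.57) fell in both; these symbols belong to histidine utilization. Of the his genes in the amino acid biosynthesis list, hisA (0.76 and 0.60), hisB (0.39 and 0.53) and hisIE (0.27 and 0.42) rose in both, while hisC (0.17 and 0.24, adjusted p = 0.244 and 0.172), hisD (−0.16 and 0.33, 0.384 and 0.131), hisG (0.41 and 0.19), hisH (0.24 and 0.54), hisF (0.82 and 0.33) and the synthetase gene hisS (−0.08 and 0.45) were called in 1 background or in neither.

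The recombinase gene recA fell in both backgrounds (log2 −1.34 and −0.51), and recN (−0.61) and uvrB (−0.47) fell in the native one. The repressor gene nagC fell in the native background (−0.49) and rose in rscS* (0.63). Of 27 anaerobic respiration and fermentation genes, 3 fell in both: napA (−1.10 and −0.41), nrfB (−0.998 and −0.538) and nrfC (−0.38 and −0.41). In the native background 12 of the 27 fell and 4 rose (camera adjusted p = 0.0625, which did not pass), and in rscS* 3 fell and 1 rose (0.416).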
